A study of Mus musculus with 11 samples.

How the data were processed

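Total RNA was sequenced from cultured adult mouse microglia, the resident macrophages of the brain. Per the labels' protocols, the cells came from the cerebrum of C57BL/6 mice aged 6 to 8 weeks and grew for 10 to 14 days with TGF-beta1 at 5 ng/ml and M-CSF at 10 ng/ml. Pam3CSK4, a synthetic lipopeptide that activates Toll-like receptor 2 (TLR2), was given at 100 ng/ml for 24 h, and interferon-gamma (IFN-gamma) at 20 ng/ml for 24 h. The combined group received both, Pam3CSK4 first. The labels give neither whether Pam3CSK4 was washed out before IFN-gamma nor when the Control and Pam3CSK4 cells were harvested relative to the others. The 11 libraries formed 4 groups: Control (n = 3), Pam3CSK4 (n = 2), IFN-gamma (n = 3) and Pam3CSK4+IFN-gamma (n = 3). Replicates 2 and 3 of the combined group carry a different last digit in the agonist's name in one label field and were taken as the same treatment as replicate 1.

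The deposited table gave a read count and an FPKM value for each of 34745 Ensembl genes in every library, per the file headers. Per the submitters' processing notes, TopHat2 2.1.0, Cufflinks 2.1.1, Cuffdiff and the mm10 build were used, with no role given for each. The counting tool, gene annotation, strand setting and handling of shared reads are not given in the sources used here. In the 6617 genes with over 200 counts in every library, the deposited FPKM equalled the deposited count divided by 1 constant per gene and by the library total, to a largest relative deviation of 2.87e-06. Gene symbols and coordinates are those of the deposited table, on mm10. Of its gene IDs, 34344 were found in GENCODE M21, all on the same chromosome, and 2 list genes were matched through that annotation's symbol and 2 more by ID because the table repeats their symbol. No per-sample column of the table was left out.

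The choices of groups, tests, gene lists, named genes and the first set of alternative settings were made before the data were examined. The planned test was limma on log2(FPKM + 1), with edgeR in its place if counts were present; the table held whole-number counts, so edgeR was used. Counts were fitted in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 and TMM scaling. All 11 libraries entered 1 fit of 4 group means without a replicate block, because no label ties replicate numbers to a shared animal, batch or day. Genes with FPKM of at least 1 in at least 2 libraries were tested (10938 genes). These held 97.97% of the counts in combined replicate 2, 98.19% in Control replicate 3 and at least 99.34% in each other library. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2 scale with their standard errors, the latter being the absolute log2 change divided by the square root of the F statistic. Comparisons were Pam3CSK4 against Control, IFN-gamma against Control, the combined group against each of the other 3, and the interaction, which is the Pam3CSK4 effect with IFN-gamma minus that without it.

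The 26 fixed gene lists covered the IFN-gamma signature, MHC class II, MHC class I, type I interferon-stimulated genes, inflammatory cytokines, TLR-induced and feedback genes, the TLR pathway, the IFN-gamma receptor pathway, homeostatic microglial genes, disease-associated microglial genes, reactive oxygen and nitrogen genes, alternative activation, complement and Fc receptors, costimulation, inflammasome and cell death, glycolysis, oxidative phosphorylation, cholesterol metabolism, cell cycle and stress response. They also covered markers of mural cells and fibroblasts, astrocytes, neurons, oligodendrocytes, endothelial cells and other immune cells. Lists with at least 5 tested members were tested with camera from limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over lists within each comparison, and again with an estimated correlation. Genes are named by a fixed rule in Pam3CSK4 against Control, IFN-gamma against Control, the combined group against IFN-gamma, and the interaction. It takes the 6 largest rises and 6 largest falls past the threshold, given a group mean of at least 5 FPKM, no overlap between the libraries compared (outside the interaction) and no predicted gene or pseudogene. It adds up to 4 members per list with the largest changes past the threshold and a panel of 22 genes whatever their result. The other comparisons are summarised by counts and lists. Of the genes this rule names, 3 are not reported here.

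Interferon-responsive genes were those at least 2-fold changed and past the threshold in the mean of both IFN-gamma groups against Control. This contrast gives both groups equal weight, but a gene changed by Pam3CSK4 alone can enter the set through the combined group and then differ between the groups. In simulated counts in which 200 genes responded alike in both groups, 188 were selected, none was called between the groups, and their median difference was -0.01; genes changed by Pam3CSK4 alone were not simulated. The tests were also run on counts simulated for the 10938 tested genes with 100 genes changed 2-fold and 100 changed 4-fold. At 4-fold, 82 were recovered in Pam3CSK4 against Control, 86 in IFN-gamma against Control, 91 in the combined group against IFN-gamma, 88 against Control, 87 against Pam3CSK4, and 79 in the interaction. At 2-fold, the recovered numbers in the same order were 50, 52, 54, 50, 43 and 14. False calls in that order were 5.71, 5.48, 4.61, 2.82, 2.26 and 2.11% of all calls.

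The alternative settings chosen then were limma on log2(FPKM + 0.1), on quantile-normalized and on median-centred values, without the intensity trend and with array weights; DESeq2 1.42.0; no filter; a mean FPKM of at least 5; a 2-fold minimum; only the groups compared; blocks by replicate number; and leaving out each library in turn. Added after seeing the data were limma with the trend, library totals or RLE factors in place of TMM, a stromal score as a covariate, limiting interferon-responsive genes to those called in IFN-gamma against Control, and leaving out together the 3 libraries with mural and fibroblast transcripts.

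Library totals ran from 15033700 to 20321000 counts. Where a group held 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with its exact 95% interval; both cover counting error only. The p-values measure the spread between these libraries only, since no label says whether replicates came from separate cultures or animals. Where leaving out a library reduced Pam3CSK4 to 1 library, that library was assumed to vary like the other groups. Values of near-identical genes, such as the H2-Q, Gbp, Tgtp, Ifi205, Serpina3g, Ccl12 and Ly6c2 families, are uncertain because the counting of shared reads is not given, and so are those of overlapping or antisense genes.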

Results

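The data are RNA sequencing profiles of adult mouse microglia in culture, left untreated or given the TLR2 agonist Pam3CSK4, IFN-gamma, or Pam3CSK4 followed by IFN-gamma (the combined group). The Control libraries held 15033700, 15820700 and 17903400 counts, the Pam3CSK4 libraries 18296200 and 15536900, the IFN-gamma libraries 16601000, 18687400 and 15097600, and the combined libraries 20176800, 20321000 and 19529700. Between 15730 and 18185 genes had a count in each library. The first 3 principal components held 37.8, 25.9 and 25.5% of the variance. The first separated the libraries given Pam3CSK4 from those not given it, and the second separated those given IFN-gamma from those not given it. The third set Control replicate 3, IFN-gamma replicate 1 and combined replicate 3 apart from the other libraries, with scores of 78.3, 59.4 and 48.0. Replicates within groups differed beyond counting noise, with a chi-square per gene of 10.8 to 111 between pairs.

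Those 3 libraries carried transcripts of mural cells and fibroblasts, the contractile and matrix-producing cells of vessel walls and meninges. The mean log2(FPKM + 1) of that marker list was 4.21 in Control replicate 3, 2.21 in IFN-gamma replicate 1 and 1.46 in combined replicate 3, and at most 0.33 in the other libraries. Smooth muscle actin, Acta2, stood at 865, 44.1 and 10.5 FPKM in the 3 libraries, and the collagen gene Col1a1 at 430.4, 11.4 and 3.26 FPKM. Not every such gene kept this order: the fibroblast gene Dcn stood at 1.05, 7.43 and 16.4 FPKM. The highest Acta2 value elsewhere was 1.41 FPKM. Of the 7 tested members none was called in Pam3CSK4 against Control, IFN-gamma against Control or the combined group against IFN-gamma, with list medians of -7.80, -3.86 and -1.76 (camera adjusted p = 0.618, 0.643 and 0.952). Counts of changed genes are therefore also given without these 3 libraries, an alternative added after seeing the data. Neuron means were 0.30 in each of those 3 libraries and at most 0.191 elsewhere. Control replicate 3 had the highest astrocyte (0.70) and endothelial (1.15) means. Of other lists, 2 of 12 astrocyte, 2 of 14 neuron and 4 of 13 oligodendrocyte genes were tested. So were 4 of 12 endothelial and 3 of 19 other immune genes, too few for list tests. In Pam3CSK4 against Control, Eno2 (neuron, 3.56), Mag (oligodendrocyte, 1.80) and Ly6c2 (other immune, 6.66) rose. Flt1 (endothelial, -3.32) fell, and no astrocyte gene was called.

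**Figure D1:**
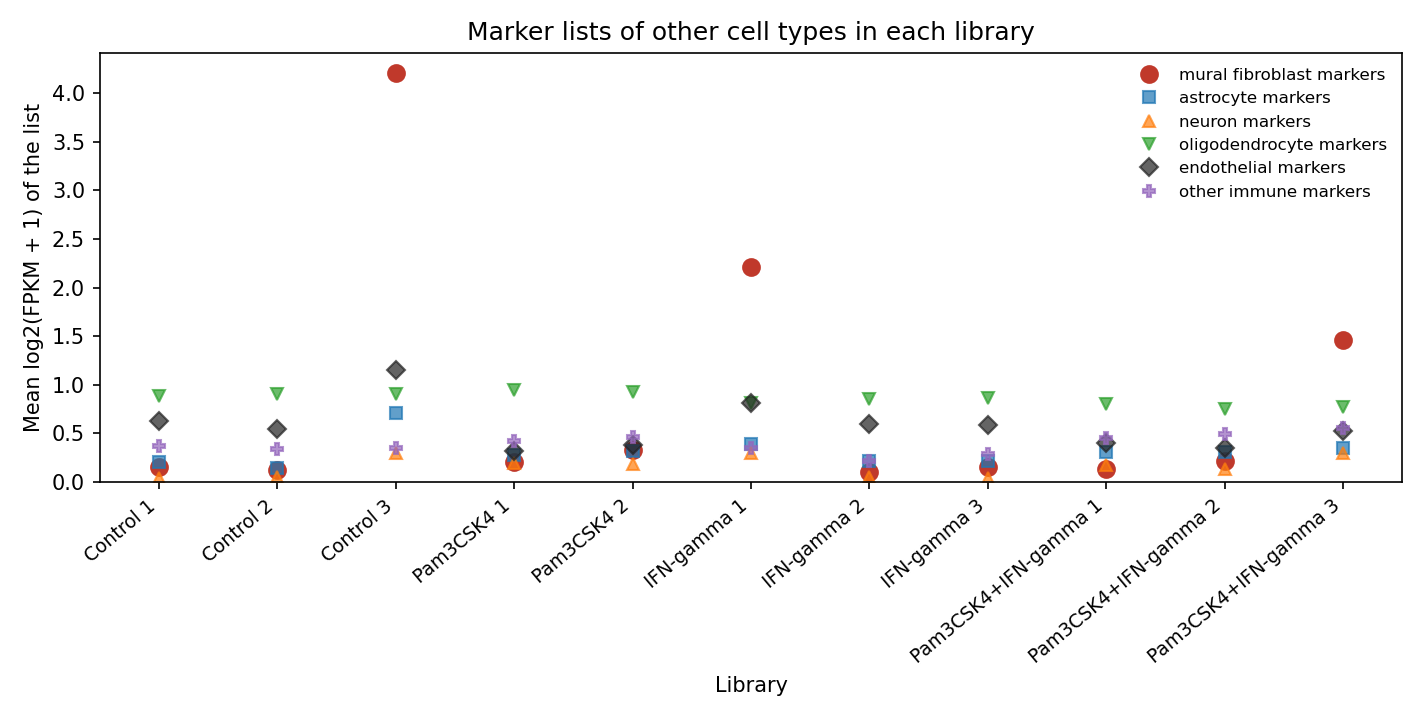
Mean log2(FPKM + 1) of 6 cell-type marker lists in each of the 11 libraries, 1 point per list and library, coloured by list. The mural and fibroblast list stands at 1.46 to 4.21 in Control replicate 3, IFN-gamma replicate 1 and combined replicate 3. Elsewhere it is at most 0.33.

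The first comparison, Pam3CSK4 against Control, asks what TLR2 activation alone did to microglial transcription. The largest rises were in genes that Control cells barely transcribed. Il12b (ENSMUSG00000004296, chromosome 11, 44400063 to 44414033), the p40 subunit shared by interleukins 12 and 23, went from 0.167 ± 0.152 FPKM (SD, n = 3) to 185 ± 108 FPKM (SD, n = 2), a log2 change of 10.05 ± 1.09 (edgeR adjusted p = 9.56e-05). The scavenger receptor gene Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024) went from 2.64 ± 1.22 FPKM (SD, n = 3) to 2276 ± 241 FPKM (SD, n = 2) (log2 change 9.75 ± 0.68), and the dicarboxylate transporter gene Slc13a3 from 0.127 ± 0.0906 FPKM (SD, n = 3) to 171 ± 79.5 FPKM (SD, n = 2) (10.37 ± 0.55). For 3 genes with 1 or 2 Control counts in all, the Pam3CSK4 to Control ratio was 3161 (95% counting interval 567 to 124903) for the axon guidance factor Draxin, 1192 (95% counting interval 329.6 to 9855) for the transcription factor Spib and 691 (95% counting interval 123 to 27359) for Ccr7, the chemokine receptor that guides migration to lymph nodes.

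The largest falls after Pam3CSK4 included the purinergic-family receptor gene Gpr34 (ENSMUSG00000040229, chromosome X, 13632089 to 13640858), from 76.4 ± 26.5 FPKM (SD, n = 3) to 0.529 ± 0.120 FPKM (SD, n = 2) (log2 change -7.20 ± 0.46, edgeR adjusted p = 5.60e-06). The low-affinity Fc receptor gene Fcgr3 went from 157 ± 20.0 FPKM (SD, n = 3) to 1.91 ± 0.249 FPKM (SD, n = 2) (-6.39 ± 0.21) and the CGRP receptor subunit gene Ramp1 fell by 7.27 ± 0.50. Nbl1, a BMP antagonist, changed by -6.89 ± 1.63 (edgeR adjusted p = 0.00813), and by -7.32 and -6.60 without Pam3CSK4 replicate 1 or 2 (adjusted p = 0.0598 and 0.0691). Glipr2 and Hbegf, an EGF-family growth factor, had fitted changes of -7.84 ± 2.78 and -7.39 ± 2.62 (adjusted p = 0.0473 and 0.0476) that rested on Control replicate 3. Without that library they were -2.78 and -1.30 (edgeR adjusted p = 0.184 and 0.316). Leaving out any Pam3CSK4 or combined library, or IFN-gamma replicate 2 or 3, also raised both adjusted p values above 0.05, as did leaving out IFN-gamma replicate 1 for Hbegf (0.0546). Their lowest and highest values among these were 0.0570 and 0.205 for Glipr2, and 0.0546 and 0.198 for Hbegf, and the Glipr2 ratio of Control to Pam3CSK4 counts was 302 (95% counting interval 83.2 to 2494).

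Inflammatory genes rose as a group after Pam3CSK4. Of 24 tested cytokine and chemokine genes, 15 rose and 2 fell, the same counts as when adjusted over the list alone, with a median log2 change of 1.98 (camera adjusted p = 1.38e-14) and 3.71 without Control replicate 3. The T-cell and monocyte chemokine gene Ccl5 went from 2.85 ± 1.16 FPKM (SD, n = 3) to 1139 ± 47.5 FPKM (SD, n = 2), a change of 8.64 ± 0.28 (edgeR adjusted p = 1.09e-07), and the neutrophil chemokine genes Cxcl3 and Cxcl2 by 8.55 ± 0.70 and 6.52 ± 0.43. Of 27 TLR-induced and feedback genes 20 rose and 0 fell (21 and 0 adjusted over the list alone; median 1.80, camera adjusted p = 5.07e-24). They included Acod1, the itaconate-producing enzyme (5.88 ± 0.14), and the lectin receptor gene Clec4e (4.84 ± 0.23), and the ratio for the anti-inflammatory cytokine gene Il10 was 343 (95% counting interval 117 to 1666). Of 20 reactive oxygen and nitrogen genes 13 rose and 1 fell, with the same counts adjusted over the list alone (median 1.15, camera adjusted p = 1.99e-10), among them superoxide dismutase 2, Sod2 (3.61 ± 0.10), and Cybb, the NADPH oxidase subunit (3.24 ± 0.16). These 3 list calls held with an estimated correlation (camera adjusted p = 0.00205, 0.00258 and 0.0354).

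Interferon-stimulated genes also rose after Pam3CSK4 without added IFN-gamma. All 30 tested type I interferon-stimulated genes rose, also when adjusted over the list alone (median 2.08, camera adjusted p = 3.70e-29, and adjusted p = 0.0774 with an estimated correlation). The antiviral effector genes Ifit1, Isg15 and Rsad2 changed by 4.42 ± 0.28, 3.55 ± 0.23 and 3.65 ± 0.29. Of 29 IFN-gamma signature genes 18 rose and 2 fell (18 and 4 adjusted over the list alone), with a median of 1.79 (camera adjusted p = 9.87e-13, and adjusted p = 0.00258 with an estimated correlation). Without Pam3CSK4 replicate 2 that median was 1.16. Of 20 MHC class I genes 12 rose and none fell, as when adjusted over the list alone, with a median of 0.65 (camera adjusted p = 2.46e-06, and adjusted p = 0.379 with an estimated correlation). Of 17 IFN-gamma receptor pathway genes 6 rose, among them the kinase gene Jak2 (2.61 ± 0.11), and 2 fell, as when adjusted over the list alone. That median was 0.22 (camera adjusted p = 0.00208, and adjusted p = 0.0949 with an estimated correlation).

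MHC class II and homeostatic microglial genes were lower after Pam3CSK4 at camera's preset correlation. Of 12 MHC class II genes 7 fell and none rose, as when adjusted over the list alone, with a median of -1.001 (camera adjusted p = 0.00208, and adjusted p = 0.433 with an estimated correlation). The peptide-exchange chaperone genes H2-DMb2 and H2-DMa changed by -4.12 ± 0.26 and -2.51 ± 0.25. Of 30 homeostatic microglial genes 25 fell and 2 rose, as when adjusted over the list alone, with a median of -1.54 (camera adjusted p = 5.48e-16, and adjusted p = 0.138 with an estimated correlation). The ATP-degrading ectoenzyme gene Entpd1 and the ADP receptor gene P2ry13 changed by -4.58 ± 0.31 and -4.18 ± 0.28. Of 25 genes of disease-associated microglia 17 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -1.14 (camera adjusted p = 1.79e-07, and adjusted p = 0.369 with an estimated correlation). The osteopontin gene Spp1 and lipoprotein lipase, Lpl, were among those that fell (-3.36 ± 0.36 and -2.89 ± 0.32).

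The cell cycle list was called in Pam3CSK4 against Control, with a median of 0.59 (camera adjusted p = 0.0157, and adjusted p = 0.743 with an estimated correlation). Of its 30 genes 8 rose and none fell (5 and 0 adjusted over the list alone), among them the replication licensing genes Mcm5 (1.88 ± 0.40) and Mcm6 (1.39 ± 0.27). The list's camera adjusted p was 0.0783 and 0.0604 without Control replicate 1 or 2, and its median was 1.20 without Control replicate 3. With the 3 libraries with mural and fibroblast transcripts left out, 25 rose and 0 fell (median 1.21, camera adjusted p = 1.01e-09). The stress response list, with 2 of 20 genes higher and a median of 0.07, was not called (camera adjusted p = 0.454) but passed without Control replicate 3 (0.75, 0.0266) and without those 3 libraries, with 13 higher (0.75, 0.00380). The remaining lists did not pass. The TLR pathway had 7 genes higher and 4 lower of 26, alternative activation 1 and 4 of 9, complement and Fc receptors 5 and 6 of 22, and costimulation 4 and 4 of 14. Their medians were 0.34, -0.25, -0.22 (with an upward test direction) and 0.20 (camera adjusted p = 0.225, 0.542, 0.814 and 0.403).

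Among the panel genes not yet given, Pam3CSK4 raised the chemokine genes Cxcl10 (6.35 ± 0.21) and Cxcl9 (2.31 ± 0.16), the cytokine genes Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007; 5.21 ± 0.31) and Il1b (1.19 ± 0.25), the costimulatory and checkpoint genes Cd40 (4.29 ± 0.20) and Cd274 (1.91 ± 0.18), and the signalling feedback gene Socs1 (3.62 ± 0.17). Inducible nitric oxide synthase, Nos2, rose by 4.97 ± 1.14, and by 8.39 without Control replicate 3, in which it stood at 4.68 FPKM. The receptor genes Ifngr1 (-1.60 ± 0.18), P2ry12 (-3.92 ± 0.47) and Trem2 (-2.39 ± 0.25) and the class II gene H2-Ab1 (-1.01 ± 0.17) fell. Tlr2 rose by 0.58 ± 0.17 (edgeR adjusted p = 0.0240), with adjusted p = 0.138 and 0.0532 without Pam3CSK4 replicate 1 or 2. Tmem119, a microglial surface protein, fell by 0.91 ± 0.29 (edgeR adjusted p = 0.0324), with adjusted p = 0.0894, 0.0751, 0.167 and 0.0941 without Control replicate 1 or 2 or Pam3CSK4 replicate 1 or 2. The class II transactivator gene Ciita held 1 count after Pam3CSK4 and 10 in Control, a ratio of 6.97 (95% counting interval 0.992 to 303). Its edgeR adjusted p of 0.0436 rose to 0.0634, 0.118, 0.0606 and 0.2502 without Control replicate 1 or 3 or Pam3CSK4 replicate 1 or 2, where its fitted change lay between -4.82 and -1.79. Il6, Irf1 and Arg1 did not pass (1.62 ± 1.39, -0.41 ± 0.16 and 1.89 ± 1.10; edgeR adjusted p = 0.375, 0.0692 and 0.195); without Control replicate 3, Il6 was 4.00 (0.0324) and Irf1 -0.50 (0.0187).

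In all, edgeR called 2188 genes higher and 2344 lower after Pam3CSK4, of which 782 and 1019 changed at least 2-fold, and camera called 11 of 21 lists. Without the 3 libraries with mural and fibroblast transcripts the counts were 2882 and 2998 genes and 15 lists. Without Pam3CSK4 replicate 2 they were 1410 higher and 1463 lower, and without Pam3CSK4 replicate 1 they were 1574 and 1561.

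**Figure D2:**
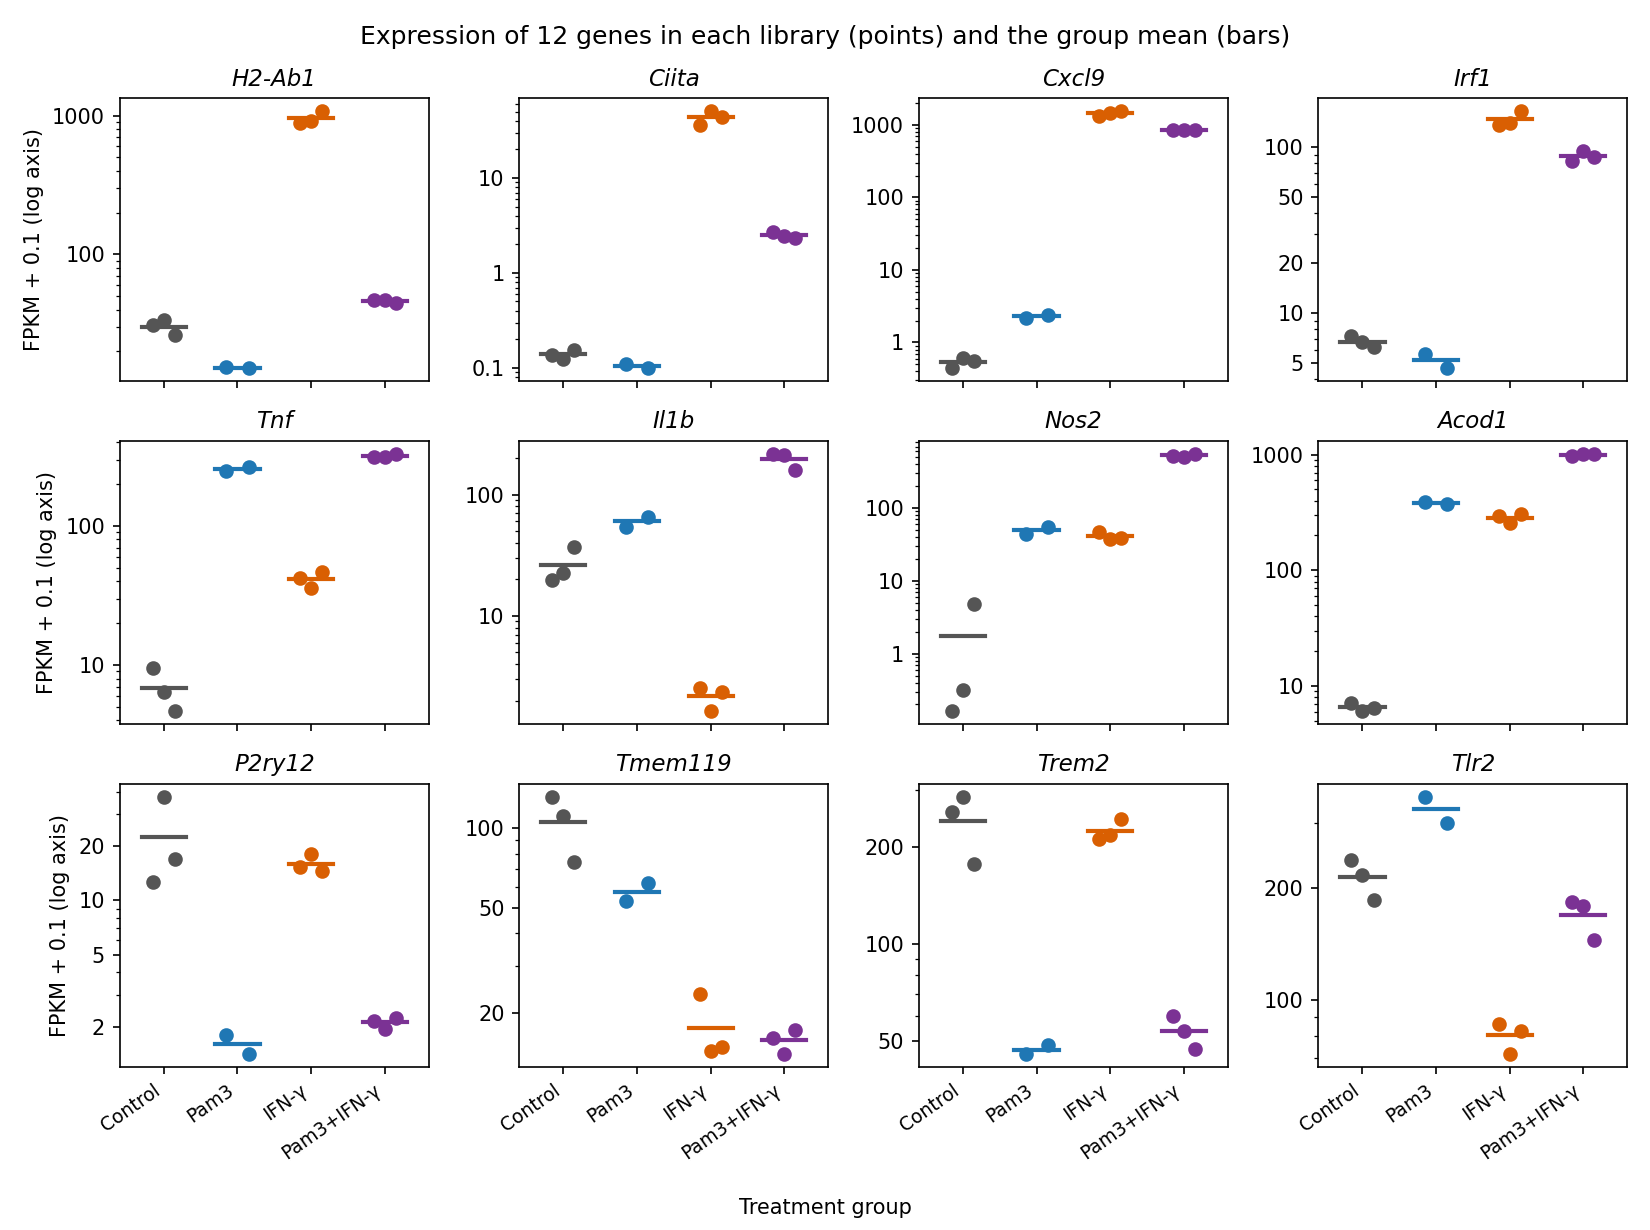
FPKM + 0.1 on a log axis for 12 panel genes in each library, 1 point per library in 4 groups, with a line at the group mean. H2-Ab1 averages 962 FPKM after IFN-gamma and 46.0 after both treatments, while Il1b averages 2.08 and 196 FPKM.

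IFN-gamma against Control asks what IFN-gamma alone did. The largest rises were Iigp1, Cxcl9, Serpina3g, Il12rb1, Pdyn and Sectm1a. The immunity-related GTPase gene Iigp1 went from 0.161 ± 0.103 FPKM (SD, n = 3) to 846 ± 91.3 FPKM (SD, n = 3), a log2 change of 12.46 ± 0.40 (edgeR adjusted p = 6.61e-08). The T-cell chemokine gene Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) went from 0.438 ± 0.0815 FPKM (SD, n = 3) to 1459 ± 118 FPKM (SD, n = 3) (11.80 ± 0.20), and the serine protease inhibitor gene Serpina3g changed by 10.67 ± 0.46. The IFN-gamma to Control ratio was 4232 (95% counting interval 759 to 167180) for Il12rb1, an interleukin 12 receptor chain with 1 Control count, and 2391 (95% counting interval 662 to 19750.5) for the opioid precursor gene Pdyn with 2. Sectm1a, with 0 Control counts, was at least 275-fold higher.

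The largest falls after IFN-gamma were Baiap2l2, Lsp1, Abca9, Cxcr4, Mamdc2 and Nr4a1. Baiap2l2, a membrane-bending adaptor, changed by -7.52 ± 0.58 and the actin-binding gene Lsp1 by -4.59 ± 0.26. The transporter gene Abca9, the chemokine receptor gene Cxcr4 and Mamdc2 changed by -4.58 ± 0.22, -4.21 ± 0.27 and -4.19 ± 0.40. The immediate-early nuclear receptor gene Nr4a1 changed by -4.18 ± 1.21 (edgeR adjusted p = 0.0206). Without Control replicate 3 or IFN-gamma replicate 2 or 3 it was -2.47, -3.70 and -3.66 (adjusted p = 0.0605, 0.0635 and 0.0552), and without IFN-gamma replicate 1 it was -6.77.

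All 29 IFN-gamma signature genes rose, also when adjusted over the list alone, with a median of 6.48 (camera adjusted p = 1.17e-126, and adjusted p = 6.12e-06 with an estimated correlation). Of 12 class II genes 10 rose and none fell, as when adjusted over the list alone (median 2.87, camera adjusted p = 1.10e-43, estimated 0.0102). Ciita (ENSMUSG00000022504, chromosome 16, 10488178 to 10527564), the class II transactivator, went from 0.0384 ± 0.0146 FPKM (SD, n = 3) to 43.7 ± 7.25 FPKM (SD, n = 3) (10.20 ± 0.28), the invariant chain gene Cd74 from 15.8 ± 0.773 FPKM (SD, n = 3) to 3207 ± 427 FPKM (SD, n = 3) (7.76 ± 0.16) and H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34263209 to 34269418) from 30.02 ± 3.78 FPKM (SD, n = 3) to 962 ± 105 FPKM (SD, n = 3) (5.09 ± 0.17). All 20 class I genes rose, also when adjusted over the list alone (median 2.18, camera adjusted p = 1.61e-33, estimated 0.0325), among them the class I transactivator gene Nlrc5 (3.80 ± 0.13) and the peptide transporter gene Tap1 (3.52 ± 0.20). Of 22 complement and Fc receptor genes 15 rose and 2 fell (17 and 2 adjusted over the list alone; median 1.19, camera adjusted p = 5.23e-12, estimated 0.0325). The complement genes C4b and Cfb changed by 8.13 ± 0.53 and 7.83 ± 0.46, and the Fc receptor gene Fcgr4 by 4.67 ± 0.22. In the IFN-gamma receptor pathway 11 of 17 genes rose and 1 fell, as when adjusted over the list alone (median 0.66, camera adjusted p = 1.05e-08, estimated 0.0125).

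Other lists passed at camera's preset correlation and not at the estimated one. Of 30 type I interferon-stimulated genes 29 rose and none fell (median 1.82, camera adjusted p = 7.31e-24, and adjusted p = 0.0584 with an estimated correlation), among them the nucleic acid sensor gene Zbp1 (4.87 ± 0.21). Of 27 TLR-induced and feedback genes 14 rose and 3 fell (median 0.72, camera adjusted p = 7.81e-06, estimated 0.0584), and of 22 inflammasome and cell death genes 14 rose and 2 fell (median 0.97, 2.53e-07, estimated 0.0584). Adjusted over the list alone, these counts were the same. Of 24 cytokine genes 11 rose and 5 fell (11 and 6 adjusted over the list alone), with a median of 1.00 (camera adjusted p = 0.00614, estimated 0.0584). That median was 2.35 without Control replicate 3 and 0.17 without IFN-gamma replicate 1. Costimulation genes rose in 7 and fell in 2 of 14 cases (8 and 2 adjusted over the list alone; median 0.98, and 1.51 without Control replicate 1; camera adjusted p = 1.58e-04, estimated 0.110). Of 20 reactive oxygen and nitrogen genes 9 rose and 3 fell (median 0.29, camera adjusted p = 0.00934, estimated 0.266), a call lost without the 3 libraries with mural and fibroblast transcripts (8 higher, 4 lower, camera adjusted p = 0.0610). Homeostatic microglial genes fell in 13 and rose in 3 of 30 cases (16 and 3 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 9.33e-04, estimated 0.485). Those that fell included Gpr34 (-4.09 ± 0.33) and the TAM receptor ligand gene Gas6 (-3.39 ± 0.20). Disease-associated microglial genes, with 7 higher and 6 lower of 25 (7 and 8 adjusted over the list alone), the TLR pathway, with 7 and 5, and alternative activation, with 4 and 1 of 9, did not pass (medians -0.05, -0.06 and 0.44; camera adjusted p = 0.643, 0.604 and 0.193). The TLR pathway's test direction was upward.

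Among the panel genes not yet given, IFN-gamma raised Socs1 (8.47 ± 0.19), Cxcl10 (7.54 ± 0.22), Acod1 (5.56 ± 0.13), the transcription factor gene Irf1 (4.55 ± 0.16), Cd40 (3.90 ± 0.19), Cd274 (3.04 ± 0.18) and Tnf (2.70 ± 0.27). It lowered the cytokine gene Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) from 26.3 ± 9.10 FPKM (SD, n = 3) to 2.08 ± 0.468 FPKM (SD, n = 3) (-3.54 ± 0.25, edgeR adjusted p = 7.46e-06), and Tmem119, Tlr2 and Ifngr1 by -2.52 ± 0.27, -1.33 ± 0.16 and -0.93 ± 0.15. Nos2 rose by 4.82 ± 1.09, and by 8.23 without Control replicate 3. Il12b (1.25 ± 1.04), P2ry12 (-0.41 ± 0.35), Trem2 (-0.02 ± 0.20) and Il6 (-1.05 ± 1.33) did not pass (edgeR adjusted p = 0.364, 0.382, 0.954 and 0.557), and Il6 was -5.52 (0.0249) without IFN-gamma replicate 1. Il10 held 0 counts after IFN-gamma and 3 in Control, too few for a fold (adjusted p = 0.0910). The arginase gene Arg1 had an edgeR adjusted p of 0.0486 (log2 change 2.92 ± 1.04) and 0.89 without IFN-gamma replicate 1 (adjusted p = 0.369). Leaving out any other library except Control replicate 3 or IFN-gamma replicate 2 or 3 also raised its adjusted p above 0.05, to at most 0.128. IFN-gamma raised 2189 genes and lowered 2361 (edgeR), of which 731 and 698 changed at least 2-fold, and camera called 14 of 21 lists; without the 3 libraries with mural and fibroblast transcripts the counts were 2508, 2663 and 13. With library totals in place of TMM factors the median change of all genes moved from -0.07 to -0.18 and the share of higher calls from 48.1 to 36.4%; with median-centred values that share was 56.6%. Among the small marker lists, 2 oligodendrocyte, 1 endothelial and 1 other immune gene rose, and 1 gene of each of these and of the neuron list fell.

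The combined group against IFN-gamma asks what earlier TLR2 activation did to IFN-gamma-treated microglia. MHC class II genes fell together. Of 12 tested members all fell, also when adjusted over the list alone, with a median of -3.72 (camera adjusted p = 2.36e-43, and adjusted p = 0.00822 with an estimated correlation). Cd74 went from 3207 ± 427 FPKM (SD, n = 3) to 95.2 ± 2.29 FPKM (SD, n = 3) (-5.09 ± 0.14), H2-Ab1 from 962 ± 105 FPKM (SD, n = 3) to 46.0 ± 1.33 FPKM (SD, n = 3) (-4.40 ± 0.17), H2-Aa from 652 ± 78.7 FPKM (SD, n = 3) to 18.6 ± 1.20 FPKM (SD, n = 3) (-5.14 ± 0.32) and Ciita from 43.7 ± 7.25 FPKM (SD, n = 3) to 2.402 ± 0.188 FPKM (SD, n = 3) (-4.20 ± 0.20, edgeR adjusted p = 7.36e-07). The IFN-gamma signature list had 13 of 29 genes lower and 4 higher (14 and 4 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 0.0234, and adjusted p = 0.0790 with an estimated correlation). Cxcl9 fell by 0.78 ± 0.12 and Cxcl10 rose by 2.55 ± 0.17. Of 20 class I genes 6 fell and none rose, as when adjusted over the list alone, and the list did not pass (median -0.25, camera adjusted p = 0.171). Mural and fibroblast markers differ between replicates of both groups, as given above, and without those 3 libraries the class II median was -3.78 and the class I list was called lower, with 9 lower and 0 higher (median -0.30, camera adjusted p = 0.0197).

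The largest rises in the combined group against IFN-gamma were mostly genes that Pam3CSK4 alone had also raised. Marco went from 3.50 ± 2.70 FPKM (SD, n = 3) to 2159.5 ± 318 FPKM (SD, n = 3) (9.25 ± 0.66, edgeR adjusted p = 9.37e-06). Slc13a3, the epithelial anchoring gene Lad1 and Il12b rose by 9.12 ± 0.52, 9.00 ± 0.96 and 8.72 ± 1.00. Ccr7, with 0 counts after IFN-gamma, was at least 178-fold higher, and the ratio for Draxin, with 2 counts, was 1363 (95% counting interval 377 to 11263). The largest falls were in Sectm1a (-7.44 ± 0.54), the antimicrobial ribonuclease gene Rnase6 (-6.51 ± 0.58), Ramp1 (-5.78 ± 0.39), the organic anion transporter gene Slco2b1 (-5.69 ± 0.35), Pdyn (-5.56 ± 0.32) and the lectin-like receptor gene Klrb1b (-5.37 ± 0.21).

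Inflammatory genes were higher in the combined group than after IFN-gamma. Of 24 cytokine genes 13 rose and 5 fell (14 and 5 adjusted over the list alone; median 3.14, camera adjusted p = 7.19e-13, estimated 0.00156). Il1b went from 2.08 ± 0.468 FPKM (SD, n = 3) to 196 ± 31.3 FPKM (SD, n = 3) (6.56 ± 0.29, edgeR adjusted p = 5.33e-07), Cxcl2 and Cxcl3 rose by 7.82 ± 0.48 and 7.22 ± 0.63, and Il10 was at least 40.9-fold higher. Of 27 TLR-induced and feedback genes 20 rose and none fell (21 and 0 adjusted over the list alone; median 1.36, camera adjusted p = 1.03e-16, estimated 0.00496), including the signalling regulators Nfkbiz (4.21 ± 0.24) and Irak3 (3.30 ± 0.16). Of 20 reactive oxygen and nitrogen genes 14 rose and 2 fell, as when adjusted over the list alone (median 0.99, camera adjusted p = 1.01e-10, estimated 0.0268), including the cystine and arginine transporter genes Slc7a11 (3.53 ± 0.13) and Slc7a2 (2.38 ± 0.11). Type I interferon-stimulated genes rose in 20 and fell in 1 of 30 cases, as when adjusted over the list alone (median 0.86, camera adjusted p = 9.36e-07, and adjusted p = 0.490 with an estimated correlation), with Rsad2 and Ifit1 at 2.95 ± 0.27 and 1.94 ± 0.24.

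Homeostatic microglial genes were lower in the combined group than after IFN-gamma at camera's preset correlation. Of 30 homeostatic genes 21 fell and 2 rose, as when adjusted over the list alone, with a median of -1.14 (camera adjusted p = 7.18e-10, and adjusted p = 0.296 with an estimated correlation). The ADP receptor gene P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871) went from 15.9 ± 1.91 FPKM (SD, n = 3) to 2.01 ± 0.148 FPKM (SD, n = 3) (-2.99 ± 0.38) and Gpr34 changed by -3.38 ± 0.34. Of 25 disease-associated microglial genes 18 fell and 3 rose (20 and 3 adjusted over the list alone; median -1.13, camera adjusted p = 4.13e-08, and adjusted p = 0.321 with an estimated correlation), including Lpl (-3.24 ± 0.27), Spp1 (-3.09 ± 0.30) and the integrin gene Itgax (-2.75 ± 0.28). Of 22 complement and Fc receptor genes 12 fell and 5 rose (13 and 5 adjusted over the list alone; median -0.71, camera adjusted p = 0.0389, and adjusted p = 0.490 with an estimated correlation). That call was lost without combined replicate 1, 2 or 3 (camera adjusted p = 0.0667, 0.0717 and 0.0567). Costimulation genes, with 2 higher and 7 lower of 14, did not pass (median -0.63, camera adjusted p = 0.114, and 0.0415 without Control replicate 3, and 0.0273 without the 3 libraries with mural and fibroblast transcripts). The TLR pathway (7 higher, 2 lower), the IFN-gamma receptor pathway (5 and 4), alternative activation (2 and 2) and inflammasome genes (3 and 6) did not pass either. Adjusted over the list alone, these counts were 8 and 2, 6 and 4, 2 and 4, and 3 and 6. Their medians were 0.13, 0.20, 0.29 with a downward test direction, and -0.10 (camera adjusted p = 0.171, 0.562, 0.952 and 0.936).

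Among the other panel genes, Tnf (2.92 ± 0.27), Cd40 (2.27 ± 0.17), Acod1 (1.81 ± 0.11), Tlr2 (1.07 ± 0.16) and Cd274 (0.70 ± 0.16) rose in the combined group against IFN-gamma. Trem2 (-2.08 ± 0.21), Ifngr1 (-0.94 ± 0.15), Irf1 (-0.74 ± 0.14) and Socs1 (-0.65 ± 0.14) fell. Nos2 stood at 37.9 to 46.4 FPKM in the IFN-gamma libraries and at 504 to 557 FPKM in the combined libraries. It rose by 3.68 ± 1.02 (edgeR adjusted p = 0.0208), with adjusted p = 0.0562, 0.0703 and 0.0748 without IFN-gamma replicate 1, 2 or 3. The same fit held the Control libraries, where Nos2 had 351 counts in replicate 3 and 4 and 14 in its group mates. Tmem119 (-0.16 ± 0.26), Il6 (3.88 ± 1.42) and Arg1 (1.39 ± 0.95) did not pass (edgeR adjusted p = 0.671, 0.0613 and 0.292). Il6 passed without Control replicate 3 (3.88, 0.0116) or IFN-gamma replicate 1 (8.35, 0.00540), and Arg1 without IFN-gamma replicate 1 (3.42, 0.0132). In all, 1856 genes were higher and 1884 lower in the combined group (edgeR), 622 and 605 of them at least 2-fold, and camera called 10 of 21 lists. Without the 3 libraries with mural and fibroblast transcripts the counts were 2251, 2140 and 16. The share of higher calls was 49.6%, 50.1% with library totals and 43.1% with median-centred values. Among the small marker lists, 1 neuron, 1 oligodendrocyte, 1 endothelial and 2 other immune genes rose, and 1 astrocyte, 2 oligodendrocyte and 1 endothelial gene fell.

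**Figure D3:**
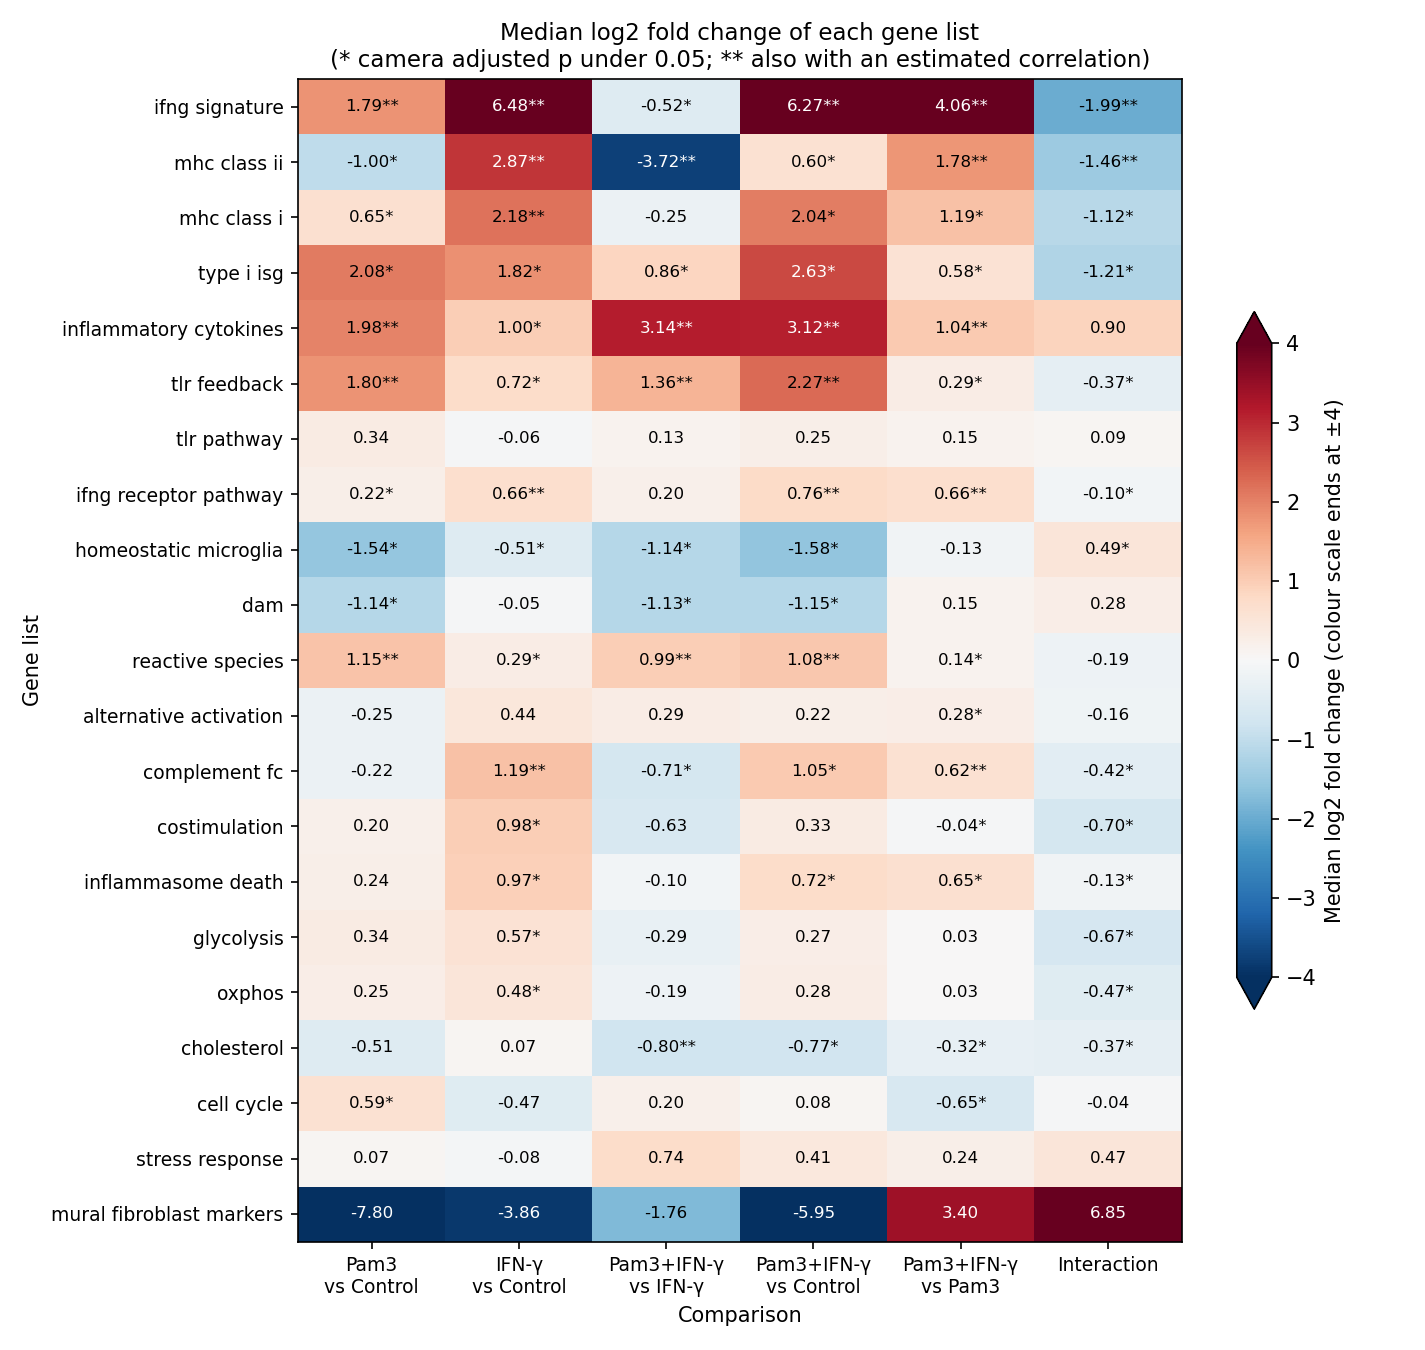
Median log2 fold change of the tested members of 21 gene lists (vertical) in 6 comparisons (horizontal) as a colour scale, with 1 asterisk where camera called the list at its preset correlation and 2 where the call also held at the estimated one. MHC class II has a median of 2.87 in IFN-gamma against Control and -3.72 in the combined group against IFN-gamma.

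Genes changed in the mean of both IFN-gamma groups against Control were compared between these groups. That mean holds a share of the Pam3CSK4 effect, so the set also takes in genes that Pam3CSK4 alone changed. Of 781 induced genes, 311 (39.8%) were higher and 154 (19.7%) lower in the combined group than after IFN-gamma, with a median difference of 0.29. Of 812 repressed genes, 77 (9.48%) were higher and 313 (38.5%) lower, with a median of -0.46. Limited to genes also called in IFN-gamma against Control, a limit added after seeing the data that favours genes moved back, 659 induced genes remained, with 202 higher and 154 lower (median 0.07), and 644 repressed genes, with 77 higher and 223 lower (median -0.28). Of the other 122 induced genes 109 were higher and 0 lower, and of the other 168 repressed genes 0 were higher and 90 lower. Without the 3 libraries with mural and fibroblast transcripts, 898 genes were induced, with 402 higher and 207 lower, and 891 were repressed, with 129 higher and 351 lower. MHC class II genes were among those moved back, and Cxcl10, Acod1 and Tnf were among those raised by both.

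The combined group against Control asks how the sequence of both treatments compares with none. IFN-gamma signature genes rose in 29 of 29 cases (median 6.27, camera adjusted p = 5.42e-82), class I genes in 19 of 20 (2.04, 2.48e-20) and type I interferon-stimulated genes in 29 of 30 (2.63, 2.35e-31), with none lower. Cytokine genes rose in 17 of 24 cases (3.12, and 5.29 without Control replicate 3; camera adjusted p = 2.33e-17), TLR-induced genes in 24 of 27 (2.27, 3.36e-23) and reactive oxygen and nitrogen genes in 14 of 20 (1.08, 3.84e-12). Class II genes split, with 6 higher and 4 lower of 12 (8 and 4 adjusted over the list alone), a median of 0.60 (camera adjusted p = 0.00160), and 0.42 (adjusted p = 0.106) without Control replicate 3. That call was lost without the 3 libraries with mural and fibroblast transcripts (0.44, 0.177). The IFN-gamma receptor pathway (0.76, 2.99e-08), complement (1.05, 5.76e-05) and inflammasome genes (0.72, 1.85e-05) were called higher. Homeostatic genes fell in 25 of 30 cases (-1.58, 1.67e-13), disease-associated genes in 19 of 25 (-1.15, 2.80e-06) and cholesterol genes in 16 of 25 (-0.77, 1.70e-04). With an estimated correlation the camera adjusted p was 0.0676 for class I, 0.0503 for type I genes, 0.388 for class II, 0.129 for complement, 0.0903 for inflammasome, 0.129 for homeostatic, 0.292 for disease-associated and 0.0660 for cholesterol genes, while the other 5 calls held. Adjusted over the list alone, 20 class I, 18 cytokine, 24 TLR-induced and 14 reactive oxygen and nitrogen genes rose, and 26 homeostatic and 19 disease-associated genes fell. Camera called 13 of 21 lists and 16 without those 3 libraries, where glycolysis, oxidative phosphorylation, cell cycle and stress response genes were also called higher (camera adjusted p = 0.0130, 0.0255, 0.0488 and 6.30e-05, against 0.0663, 0.0718, 0.714 and 0.133 with them). edgeR called 2556 genes higher and 2646 lower, 1001 and 1001 of them at least 2-fold, and 2958 and 2879 without the 3 libraries with mural and fibroblast transcripts. With library totals in place of TMM factors the median change of all genes was -0.13 and the share of higher calls moved from 49.1 to 39.3%; with median-centred values it was 51.1%.

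The combined group against Pam3CSK4 asks what IFN-gamma did to microglia already given the TLR2 agonist. These groups may also differ in time in culture, because the labels do not give when the Pam3CSK4 cells were harvested. IFN-gamma signature genes rose in 28 of 29 cases (median 4.06, camera adjusted p = 3.96e-171), class II genes in 9 of 12 (1.78, 3.06e-29), IFN-gamma receptor pathway genes in 7 of 17 (0.66, 3.10e-08) and complement genes in 9 of 22 (0.62, 6.53e-15), with none lower. Cytokine genes rose in 8 and fell in 2 of 24 cases (1.04, and 0.54 without combined replicate 3; camera adjusted p = 0.00191). These 5 calls held with an estimated correlation. Adjusted over the list alone, 29 signature, 9 class II, 8 receptor pathway, 9 complement and 8 cytokine genes rose. Class I (1.19), type I (0.58), inflammasome (0.65), TLR-induced (0.29), reactive oxygen and nitrogen (0.14) and alternative activation genes (0.28) were called higher (camera adjusted p = 1.07e-22, 1.54e-05, 3.81e-07, 0.0282, 0.00578 and 0.00281), with adjusted p = 0.0654, 0.457, 0.0654, 0.271, 0.271 and 0.140 with an estimated correlation. Without Pam3CSK4 replicate 1 the TLR-induced list had a median of 0.16 (camera adjusted p = 0.0591). The medians of the TLR-induced, reactive and alternative activation lists were 0.15 and 0.43 (TLR-induced and alternative) without combined replicate 2, 0.15 (TLR-induced) without replicate 3 and 0.09 (reactive) without replicate 1. The alternative activation call was lost without the 3 libraries with mural and fibroblast transcripts (4 higher, 1 lower, camera adjusted p = 0.117). Costimulation was called upward (camera adjusted p = 0.0397, estimated 0.449) with a median of -0.04, below 0. Without Control replicate 1, Pam3CSK4 replicate 1 or 2, or IFN-gamma replicate 2 or 3 it was not called (camera adjusted p = 0.0679, 0.136, 0.0850, 0.0630 and 0.0778), and its median ran from -0.23 to 0.19. It was not called without those 3 libraries either (0.312), and stress response genes were (median 0.36, 0.00852, against 0.214 with them). Cholesterol genes fell in 5 of 25 cases (-0.32, 3.36e-04, estimated 0.0654), and the cell cycle list was called lower (-0.65, 2.20e-04, estimated 0.560) with no gene passing, and 24 of 30 lower without the 3 libraries with mural and fibroblast transcripts.

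Against Pam3CSK4 alone, 663 genes were higher and 332 lower in the combined group (edgeR), 328 and 104 of them at least 2-fold. Without the 3 libraries with mural and fibroblast transcripts the counts were 1200 and 922. Without Control replicate 3 alone they were 1185 and 820, without Pam3CSK4 replicate 1 308 and 103, and without Pam3CSK4 replicate 2 302 and 103. Without combined replicate 1, 2 or 3 there were 161, 148 and 186 lower genes. Camera called 14 of 21 lists, 13 without the 3 libraries. With library totals in place of TMM factors the median change of all genes was -0.10 and the share of higher calls moved from 66.6 to 47.1%; with quantile-normalized values it was 55.6% and with median-centred values 62.01%.

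The interaction asks whether the effect of Pam3CSK4 differed with and without IFN-gamma. The labels do not give when the Pam3CSK4 cells were harvested relative to the combined group, which received IFN-gamma after Pam3CSK4. A difference in time since Pam3CSK4 therefore cannot be told apart from an effect of IFN-gamma. Antigen presentation and interferon genes had lower Pam3CSK4 effects with IFN-gamma. Class II genes had a lower effect in 7 of 12 cases and a higher one in none, as when adjusted over the list alone (median -1.46, camera adjusted p = 7.45e-25, and adjusted p = 0.0489 with an estimated correlation). H2-Ab1 had an interaction of -3.39 ± 0.22 (edgeR adjusted p = 5.30e-05): it fell by 1.01 after Pam3CSK4 alone and by 4.40 after Pam3CSK4 with IFN-gamma. IFN-gamma signature genes had a lower effect in 18 of 29 cases and a higher one in none, as when adjusted over the list alone (median -1.99, camera adjusted p = 6.81e-36, and adjusted p = 1.71e-04 with an estimated correlation). The pro-inflammatory cytokine genes went both ways. Il1b had an interaction of 5.36 ± 0.37 (edgeR adjusted p = 7.24e-05) and Tnf of -2.29 ± 0.37 (0.00447). Among the largest positive interactions were Itgam, Il1b, Baiap2l2, the Notch target gene Hes1 and the sphingosine phosphate receptor gene S1pr1 (4.02 ± 0.29). The deposited table repeats the symbol Itgam, so its entry was settled by gene ID, and reads shared between entries were not tested. The Baiap2l2 call did not hold in every alternative. Among the largest negative ones were the chemokine gene Ccl22 (-8.11 ± 0.74), Ifi205 (-7.87 ± 0.40), the DNA-degrading enzyme gene Dnase1l3 (-6.73 ± 0.66) and the complement gene Cfb (-5.83 ± 0.54).

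Itgam, the integrin alpha M gene, had an interaction of 5.55 ± 1.40 (edgeR adjusted p = 0.0276), with adjusted p = 0.0833, 0.140, 0.0560 and 0.0543 without Pam3CSK4 replicate 1 or 2 or combined replicate 2 or 3. Sectm1a and Pdyn had fitted interactions of -9.77 ± 1.94 and -6.01 ± 1.65 (adjusted p = 0.0167 and 0.0376) that depend on the prior count, because both were near 0 counts without IFN-gamma. Without Pam3CSK4 replicate 2 Sectm1a was -7.44 (adjusted p = 1.00) and without Pam3CSK4 replicate 1 Pdyn was -2.86 (0.933). Leaving out any other library except Pam3CSK4 replicate 2 or IFN-gamma replicate 1 or 2 also raised the edgeR adjusted p of Pdyn to at least 0.05, the highest being 0.0666. Among panel genes that did not pass, Nos2 was -1.29 ± 1.39 (edgeR adjusted p = 0.557) and -4.70 (5.15e-05) without Control replicate 3. Without that library Ifngr1, Tlr2, Tmem119 and Trem2 also passed, at 0.81, 0.62, 0.99 and 0.53, against 0.66, 0.49, 0.75 and 0.31 with it. Il6 was 2.26 ± 1.96 and 6.73 (0.0482) without IFN-gamma replicate 1. Il12b (-1.33 ± 1.29), Irf1 (-0.33 ± 0.21), P2ry12 (0.93 ± 0.54) and Arg1 (-0.50 ± 1.44) did not pass either (edgeR adjusted p = 0.512, 0.314, 0.273 and 0.841). Ciita, with 1 count after Pam3CSK4, had a fitted value of -1.67 ± 1.28 (edgeR adjusted p = 0.592) that depends on the prior count and was 0.63 without Pam3CSK4 replicate 1. It passed in the 6 limma alternatives and in none of the others (adjusted p over the alternatives 2.39e-07 to 0.779), so whether its Pam3CSK4 effect differs is left open. Il10 had a fitted value of 0.21 (edgeR adjusted p = 0.587) that depends on the prior count, since IFN-gamma libraries held 0 counts. In the 6 limma alternatives its sign was reversed, at -2.60 to -2.40 (limma adjusted p at most 0.00607), so it is left open too.

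edgeR called 876 genes with a higher and 876 with a lower Pam3CSK4 effect under IFN-gamma, 451 and 335 of them at least 2-fold, and camera called 13 of 21 lists. Without the 3 libraries with mural and fibroblast transcripts the counts were 1601, 1499 and 14, the cell cycle list being called lower (13 of 30 genes, median -0.57, camera adjusted p = 2.49e-06, against 3 genes, -0.04 and 0.0574 with them). Without Control replicate 3 alone they were 1656 and 1576 genes, without Pam3CSK4 replicate 1 485 and 563, without Pam3CSK4 replicate 2 307 and 357, without IFN-gamma replicate 3 605 and 567, and without combined replicate 1, 2 or 3 490, 503 and 625 higher and 503, 549 and 595 lower. With median-centred values 35.1% of calls were higher and with library totals 51.8%, against 50% here.

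Pairs of comparisons that share no library were set side by side across genes, which are not independent replicates. The log2 effects of Pam3CSK4 without and with IFN-gamma correlated with Pearson's r = 0.649 and Spearman's rho = 0.568 over 10938 genes. Of the genes, 2334 were called in both (1550 for independent lists), 1066 being higher in both (371) and 1082 lower in both (404). Marco, Slc13a3, Lpl and Spp1 were among these. The effects of IFN-gamma without and with earlier Pam3CSK4 correlated with r = 0.372 and rho = 0.319, with 777 genes called in both (414), 517 higher in both (133) and 193 lower in both (71.7). Without the 3 libraries with mural and fibroblast transcripts, 3112 genes were called for Pam3CSK4 in both settings and 1529 for IFN-gamma (2360.5 and 1003 for independent lists). The correlations were then r = 0.663 and rho = 0.532 for Pam3CSK4, and r = 0.559 and rho = 0.329 for IFN-gamma. With the stromal score as a covariate they were 0.648 and 0.574, and 0.530 and 0.345, so the r for IFN-gamma depends on these libraries.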

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

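Of the tests weighed here, those of a response to the treatments, of swapped libraries, of a general loss of the interferon response and of the Ciita transcript were chosen after the result was seen, as was leaving out 3 libraries together.

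The effect of Pam3CSK4 differed with and without IFN-gamma for many genes, by the interaction test of edgeR: it was higher with IFN-gamma for 876 genes and lower for 876. A difference in time since Pam3CSK4 cannot be told apart from an effect of IFN-gamma, because the labels leave the Pam3CSK4 harvest time open. The values below are the difference between both effects on the log2 scale. Of the chemokine genes, Ccl22 had -8.11, Cxcl10 -3.80 and Cxcl9 -3.09. Of the cytokine genes, Il1b had 5.36 and Tnf -2.29. The immune regulators Socs1, Cd40, Cd274 and Acod1 had -4.28, -2.02, -1.22 and -4.07. A negative value on this log2 scale does not mean a lower level with both treatments. Cd40, Cd274, Acod1, Cxcl10 and Tnf were higher in every combined library than in any other library. For Cd40 these were 34.3 to 41.1 FPKM against at most 11.3. Socs1, Cxcl9 and H2-Ab1 were lower in every combined library than in any IFN-gamma library. The class II gene H2-Ab1 had -3.39, the complement gene Cfb -5.83, Ifi205 -7.87, Dnase1l3 -6.73 and Ly6c2 -3.48. For Ly6c2 the edgeR and limma adjusted p ranged over the alternatives from 3.52e-05 to 0.962, and 4 of them reversed its sign. The call for Baiap2l2, listed further on, did not hold in every alternative. Sectm1a had -9.77 and Pdyn -6.01, both near 0 counts without IFN-gamma, so that these fitted values depend on the prior count. Without Pam3CSK4 replicate 2 Sectm1a had -7.44 (edgeR adjusted p = 1.000, over the alternatives 4.59e-07 to 1.000). Without Pam3CSK4 replicate 1 Pdyn had -2.86 (edgeR adjusted p = 0.933, over the alternatives 7.73e-07 to 0.933), and it also missed the threshold without Control replicate 1, 2 or 3 (0.0559, 0.0602 and 0.0666), IFN-gamma replicate 3 (0.0501) or combined replicate 1, 2 or 3 (0.0653, 0.0648 and 0.0530). The adhesion gene Itgam had 5.55 (not past the threshold without either Pam3CSK4 library or combined replicate 2 or 3, with edgeR adjusted p = 0.0833, 0.140, 0.0560 and 0.0543, over the alternatives 5.33e-04 to 0.140), Baiap2l2 4.66, Hes1 4.09 and S1pr1 4.02. Without Control replicate 3 the higher and lower counts were 1656 and 1576, without Pam3CSK4 replicate 1 485 and 563, without Pam3CSK4 replicate 2 307 and 357, without IFN-gamma replicate 3 605 and 567, and without combined replicate 1 or 2 490 and 503 higher and 503 and 549 lower.

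The same difference was called by camera for 13 gene lists. Median differences were -1.99 for the IFN-gamma signature, -1.46 for MHC class II, -1.12 for MHC class I and -1.21 for type I interferon-stimulated genes. They were -0.70 for costimulation, -0.42 for complement and Fc receptors (camera adjusted p = 0.105 without Control replicate 3, over the alternatives 0.00167 to 0.153), -0.67 for glycolysis, -0.47 for oxidative phosphorylation and -0.37 for cholesterol metabolism. The homeostatic list had 0.49, from 0.29 without Control replicate 2 to 0.84 without Control replicate 3. TLR-induced and feedback genes had -0.37, and -0.15 without IFN-gamma replicate 3. The IFN-gamma receptor pathway had -0.10, and without Control replicate 1 or 2 -0.19 and -0.16, without Pam3CSK4 replicate 1 or 2 -0.06 and -0.17, without IFN-gamma replicate 1, 2 or 3 -0.19, -0.16 and -0.04, and without combined replicate 3 -0.16. Inflammasome genes had -0.13, and without Control replicate 1 or 2 -0.21 and -0.20, and without Pam3CSK4 replicate 1 or 2 -0.25 and -0.04. With an estimated correlation the IFN-gamma signature and MHC class II calls held (adjusted p = 1.71e-04 and 0.0489), and the other 11 did not, the lowest of their camera adjusted p values being 0.0798.

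MHC class II genes were lower after Pam3CSK4 and IFN-gamma than after IFN-gamma alone, with a median of -3.72. The median change of the IFN-gamma signature was 0.141 times that of the class II list. This ratio cannot decide on a general loss of the interferon response. Pam3CSK4 alone raised the signature (median 1.79) and lowered class II genes (-1.001), and the interaction medians were -1.99 and -1.46. Stromal cells mixed into 3 libraries are argued against by a class II median that was 1.02 times as large without them. A candidate explanation that stays open is less transcript of the transactivator Ciita, which fell by 4.20. The 9 class II structural, invariant chain and chaperone genes had a median of -4.40 (-5.14 to -2.31) and Ctss and Ifi30, which IFN-gamma also induces by other routes, a median of -1.11, a difference of -3.29. Not all values go with this explanation. Ciita held only 10 counts in Control and 1 after Pam3CSK4 alone, yet 7 of 12 class II list genes fell there, Ciita among them. In the combined libraries Ciita stood at 2.23 to 2.60 FPKM, against at most 0.0532 in Control. Of the 12 list genes, however, 6 were higher and 4 lower than in Control. The Ciita hypothesis was found and tested on the same libraries, earlier Pam3CSK4 is the only difference the labels give between the groups, and reads shared between class II paralogs were not tested.

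Mural and fibroblast transcripts stood out in Control replicate 3, IFN-gamma replicate 1 and combined replicate 3. A response of the list to the treatments is argued against by the highest list mean lying in an untreated library, 2.00 above the next on the log2 scale. Single genes did not all keep this order. Dcn was highest in combined replicate 3, at 16.4 FPKM against 0.0476 and 0.307 in its group mates, and stood at 1.05 in Control replicate 3. A swap between Control and the groups given IFN-gamma is argued against by their IFN-gamma signature means. These lay within 0.127 of their group mates' while Control and IFN-gamma groups lay 4.08 apart. That gap does not separate the IFN-gamma and combined groups. Class II list means were 7.50 in IFN-gamma replicate 1 (7.61 and 7.70 in its group mates) and 4.67 in combined replicate 3 (4.67 and 4.65), so each lay near its own group mates. Stromal cells mixed into those libraries stay possible: of 336 genes at least 4-fold higher in Control replicate 3 than in both its group mates, 75% were at least 2-fold higher in IFN-gamma replicate 1 and 41.4% in combined replicate 3, against 0.689 and 0.208% of other genes. The lower share lies between the 50% set for mixing and the 20% set against it, so the test left it undecided.

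The 6 libraries of 2 groups of 3 can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4550 called genes in IFN-gamma against Control, 3740 in the combined group against IFN-gamma and 5202 in the combined group against Control, and in each comparison 1 of the 10 splits, the real one, gave as many. The highest count of any other split was 1, 1 and 2.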

How the results depend on the processing

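The alternatives using limma with the trend, library totals, RLE factors, the stromal score as a covariate, interferon-responsive genes limited to those called in IFN-gamma against Control, and 3 libraries left out together were chosen after seeing the data. Of 421 results for named genes, 397 were called; leaving out single libraries kept 333 of these called throughout, lost 64 at least once, added 12 and reversed none. The other alternatives kept 347, lost 50 at least once, added 15 and reversed 2. Of 126 list results 75 were called; single libraries kept 69, lost 6, added 17, and the other alternatives kept 61, lost 14, added 23, with none reversed. DESeq2 gave no adjusted p for 13 gene results. Depth limits genes near 0 counts, whose fitted values depend on the prior count: setting members at 0 counts to their bound shifted no list median in the 4 list results that hold one (largest shift 0). Counts for RLE factors stayed within 1.5 times the values reported.

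The interaction of Il10, 0.21 as reported, was -2.59 with limma on log2(FPKM + 0.1), -2.40 on quantile-normalized and -2.60 on median-centred values, -2.54 without the trend, -2.59 with array weights and -2.54 with the trend; IFN-gamma libraries held 0 counts of it. That of Ly6c2, -3.48 as reported, was 0.13 with quantile-normalized values, 0.023 without the trend, 0.074 with array weights and 0.023 with the trend. The cause was not tested for Ly6c2.

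Stricter filters test or keep fewer genes by construction, and so does limiting interferon-induced genes to those called in IFN-gamma against Control (202 higher, 311 reported). With a mean FPKM of at least 5, higher and lower counts were 1327 and 1460 in Pam3CSK4 against Control, 1357 and 1527 in IFN-gamma against Control, 1235 and 1215 in the combined group against IFN-gamma, and 1539 and 1590 against Control; interferon-induced genes had 202 higher and 95 lower, and repressed genes 35 and 143. With at least 2-fold, they were 782 and 1019, 731 and 698, 622 and 605, 1001 and 1001, 328 and 104 against Pam3CSK4, and 451 and 335 in the interaction; 101 induced genes were lower and 36 repressed genes higher. Without a filter the interaction had 441 higher genes and the combined group against Pam3CSK4 193 lower.

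For the following the cause was not tested. With only the groups compared, counts were 1314 and 1328 in Pam3CSK4 against Control, 1444 lower in IFN-gamma against Control, and 1345 and 969 in the combined group against Pam3CSK4. Array weights gave 1611 and 1976 in the interaction and 1123 and 2210 in the combined group against Pam3CSK4. Leaving out the 3 libraries with stromal transcripts gave 1601 and 1499, and 1200 and 922, with 16 lists called in the combined group against IFN-gamma and 129 repressed genes higher. The stromal score gave 1613 and 1517, and 1223 and 875. Lower genes in the combined group against Pam3CSK4 (332 reported) were 653 with limma on log2(FPKM + 0.1), 700 without the trend, 740 with it, 600 with DESeq2 and 660 with library totals. Repressed genes higher after Pam3CSK4 (77 reported) were 38 without the trend, 39 with it, 29 with quantile-normalized and 22 with median-centred values, the last with 175 lower (313 reported).

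The replicate numbers were not taken as pairs. Of 15 pairs of libraries with the same number, 6 had deviations correlated above 0.1 (range -0.72 to 0.71), and 2 libraries correlated best with their own number. With a replicate block by title number the lower count in the combined group against Pam3CSK4 was 196, and with a replicate block by sample number position it was 215; no other count of genes or lists moved by over 1.5 times.

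Leaving out each library in turn gave these lowest and highest counts of higher and of lower genes: Pam3CSK4 against Control 1410 to 2748 and 1463 to 2872, IFN-gamma against Control 1772 to 2607 and 1829 to 2729, the combined group against IFN-gamma 1356 to 2438 and 1327 to 2461, against Control 2163 to 3036 and 2156 to 3018, against Pam3CSK4 302 to 1185 and 103 to 820, and the interaction 307 to 1656 and 357 to 1576. Each of these highest counts came without Control replicate 3. Called lists, in that order, ran from 10 to 14, 14 to 14, 9 to 13, 13 to 16, 12 to 14 and 13 to 15. Interferon-induced genes higher in the combined group ran from 275 to 408 and lower from 121 to 205, and repressed genes higher from 53 to 97 and lower from 246 to 375.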

Other observations

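The ranges over the alternatives given here include limma with the trend, library totals, RLE factors, the stromal score and 3 libraries left out together, which were chosen after the result was seen.

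Glycolysis and oxidative phosphorylation genes were higher after IFN-gamma, at camera's preset correlation. After IFN-gamma alone 15 of 22 glycolysis genes rose and 1 fell (median 0.57, camera adjusted p = 1.60e-04, and adjusted p = 0.0584 with an estimated correlation), among them the hexokinase genes Hk3 (3.54 ± 0.17) and Hk2 (1.10 ± 0.13). Of 32 oxidative phosphorylation genes 23 rose and 1 fell (25 and 1 adjusted over the list alone; median 0.48, camera adjusted p = 8.58e-05, and adjusted p = 0.338 with an estimated correlation), among them Ndufs3, a subunit of complex I (1.05 ± 0.09), and cytochrome c, Cycs (1.28 ± 0.13). After Pam3CSK4 alone 11 glycolysis genes rose and 3 fell, and 13 oxidative phosphorylation genes rose and 0 fell, but neither list passed (medians 0.34 and 0.25, camera adjusted p = 0.0564 and 0.0564). Both passed without Pam3CSK4 replicate 1 (0.0170 and 0.0256), IFN-gamma replicate 2 (0.0394 and 0.0290) or 3 (0.0297 and 0.0146) or combined replicate 1 (0.0426 and 0.0365) or 2 (0.0398 and 0.0398), and glycolysis also without Control replicate 3 (0.0271). The camera adjusted p ranged over the alternatives from 2.60e-04 to 0.142 for glycolysis and from 1.91e-05 to 0.202 for oxidative phosphorylation, and was 0.0155 and 0.0253 without the 3 libraries with mural and fibroblast transcripts. In the combined group against IFN-gamma, 9 glycolysis genes fell and 2 rose, and 8 oxidative phosphorylation genes fell and none rose. Neither list passed (medians -0.29 and -0.19, camera adjusted p = 0.114 and 0.0732), though glycolysis passed without Control replicate 3 (0.0425, over the alternatives 0.00995 to 0.151). Oxidative phosphorylation passed without Pam3CSK4 replicate 1 or 2 (0.0411 and 0.0424), IFN-gamma replicate 1 or 2 (0.0346 and 0.0225) or combined replicate 2 (0.0393, over the alternatives 0.00306 to 0.157). Leaving out those 3 libraries together, both passed (0.00995 and 0.00691).

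Cholesterol genes fell where Pam3CSK4 preceded IFN-gamma. In the combined group against IFN-gamma 18 of 25 fell and 2 rose, as when adjusted over the list alone (median -0.80, camera adjusted p = 5.42e-07, and adjusted p = 0.0268 with an estimated correlation). The desaturase gene Scd2 changed by -1.93 ± 0.16, while the members that rose were Abca1, the cholesterol exporter (2.81 ± 0.14), and Nr1h3, which encodes the sterol-sensing receptor LXR-alpha (2.07 ± 0.24). After Pam3CSK4 alone 15 fell and 3 rose (median -0.51, camera adjusted p = 0.0564), a list that passed without Control replicate 3 (0.0176), Pam3CSK4 replicate 1 (0.0425), IFN-gamma replicate 2 or 3 (0.0394 and 0.0297) or combined replicate 1 or 2 (0.0415 and 0.0398, over the alternatives 0.00482 to 0.107), and without the 3 libraries with mural and fibroblast transcripts (0.0170). After IFN-gamma alone 6 rose and 4 fell (median 0.07, camera adjusted p = 0.882). Cell cycle genes did not pass after IFN-gamma (2 higher, 3 lower of 30, 1 and 0 adjusted over the list alone, median -0.47, camera adjusted p = 0.604) or in the combined group against IFN-gamma (4 higher, 0 lower, 0.20, 0.240), though they passed in the latter without IFN-gamma replicate 1 (0.65, 0.0343, over the alternatives 0.00751 to 0.676). With the 3 libraries with mural and fibroblast transcripts left out, 8 cell cycle genes were higher and 10 lower after IFN-gamma (camera adjusted p = 0.867), and 12 higher and 1 lower in the combined group against IFN-gamma (0.00751). Stress response genes did not pass after IFN-gamma (5 higher, 3 lower of 20, median -0.08 with an upward test direction, camera adjusted p = 0.866). In the combined group against IFN-gamma 7 rose and 1 fell (median 0.74, camera adjusted p = 0.0970), and the list passed without Control replicate 3 or Pam3CSK4 replicate 1 or 2 (0.0325, 0.0491 and 0.0468, over the alternatives 1.39e-04 to 0.302), and with 13 genes higher without those 3 libraries (1.39e-04).

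Single receptor and ligand genes not yet described also changed. The TLR gene Tlr12 rose by 5.29 ± 0.33 after IFN-gamma and was -2.55 ± 0.28 in the combined group against IFN-gamma. The lipopolysaccharide co-receptor gene Cd14 changed by -2.47 ± 0.31 and 3.86 ± 0.33, and the TNF-family ligand gene Tnfsf14 by 2.27 ± 0.55 and -2.60 ± 0.56. The costimulatory gene Cd86 and the inhibitory receptor gene Havcr2 changed by -1.79 ± 0.15 and -1.85 ± 0.19 in the combined group against IFN-gamma.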
